A study of Mus musculus with 18 samples.

How the data were processed

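Messenger RNA was measured in brains of young and old male mice that drank apigenin or vehicle, in 18 libraries of polyadenylated RNA, from whole brains and 1 per mouse per the labels. Per the labels' protocols, RNA was isolated with a column kit and libraries were made with oligo-dT beads and a TruSeq kit. Per the submitters' processing notes, STAR, DESeq2 and build mm10 were used, with versions not given. The counting program, the annotation and whether strand was used in counting are not given in the sources used here. The table the authors deposited holds a normalised signal per gene and library, which is the gene's read count divided by a factor of its library. This reading comes from the values: each library's values are whole multiples of what 1 read is worth, and 100% of values above 0 came out as whole reads within 0.01 of a read. The deposited columns sum to nearly equal totals, while the recovered reads sum to 28171596 to 41145635 per library, so depth was recovered from the steps. At this depth counting error is large for genes near the filter, a mean of 10, and smaller for abundant genes.

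The table has 24411 rows. The last 6 were left out because only 1 column keeps its own step in them, 4 cells are blank, and 24405 rows were kept. In the column of young apigenin replicate 3 the values were displaced against the gene names, by up to 4 rows, after Mrpl14, with 14029 rows in place before that break and 16 in place after it (Sepp1 to Septin9). Its median correlation with the other libraries was 0.806, where the lowest among the rest was 0.99, and this library was left out of the main comparisons. Putting the displaced values back in place was an added alternative, chosen after seeing the data, with 24072 rows in the realigned column, those in place included, and r = 0.995 with the mean of the intact libraries. The realignment was tested on simulated data, on 5 columns with known displacements, with 0 values misplaced. The design had assumed all 18 libraries and was otherwise kept, so the young apigenin group holds 3 libraries. No pair of libraries of a group agreed within sampling noise: over 29 pairs the chi-square per degree of freedom was 3.94 to 90.84.

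Tests used limma 3.58.1 in R 4.3.3 on log2(value + 1), with 1 fit of 4 group means over the 17 libraries and a mean-variance trend, for the 15808 genes with a mean of at least 10. The comparisons were old against young vehicle mice, apigenin against vehicle in old and in young mice, old against young apigenin mice, the interaction, and pooled aging. P-values were two-sided with Benjamini-Hochberg adjustment and a threshold of 0.05. The groups, comparisons, tests, gene lists, naming rule and most of the other settings tried were set before the data were examined. Of 48 fixed gene lists, 44 had at least 5 measured genes and were tested with limma's camera at a preset correlation of 0.01, then with an estimated correlation and with fry. The 4 not tested were T cells (3 of 18 genes measured), B and plasma cells (2 of 15), pituitary (4 of 11) and mitochondrially encoded genes (0 of 15). Exact permutation tests compared list means between groups. Opposition to aging was tested by exact reassignment of the mice of 1 age to the arms, which leaves the age difference in place, since the age difference used for young mice takes the mean of all 7 young libraries.

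Named genes followed a rule. Per comparison these were the 10 higher and 10 lower genes with the smallest adjusted p among those passing, without predicted genes and pseudogenes, or the 5 on each side with the smallest unadjusted p where none passed. Up to 4 genes with the smallest p were taken from each list that passed or is described, and 30 genes were fixed for ageing and apigenin roles, of which 27 were measured. A few genes that the rule names are not reported here. Coordinates came from a GRCm38 annotation, in which 15190 of the 15808 symbols (96.1%) were found. AF251705, Fam212a and Ctgf were not among them, and Nnt has 2 overlapping gene models there.

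The gene tests were tested on simulated data drawn from the real means and depths with 200 changed genes. Genes were drawn independently, so variation that many genes of a library share was not simulated, and the shares called in the real data may differ. For old against young vehicle mice (15759 genes simulated) 58.2% of genes changed 1.5-fold and 86.4% of those changed 2-fold were called, with 6 false calls. The shares at 1.5-fold were 71.6% for apigenin in old mice (15746 genes), 56.7% in young mice (15744), 49.3% for age in apigenin mice (15731), 25.4% for the interaction (15740) and 79.1% for pooled aging (15737). On 15808 simulated genes of the vehicle age comparison edgeR called 102 of 200 changed genes with 6 false calls, and DESeq2 123 with 26. For the vehicle age comparison camera with the preset correlation, camera with an estimated one and fry each called 0 of 440 unchanged lists and a shift of 0.3 in 10 of 10 simulated sets, in which genes vary independently. Exact permutation of list means gave an unadjusted p under 0.05 for 21 of the 440 unchanged lists and for the shifted list in 10 of 10 sets. In the real data camera with the preset correlation passed a median of 16 of 44 lists over other splits of the vehicle libraries. The length matching was not tested on simulated data. The opposition test in old mice gave an exact p under 0.05 in 1 of 20 sets without opposition and detected all 20 sets with an opposition of 0.5 of the age difference. Genes varied independently in these sets as well. The test in young mice was not tested on simulated data.

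Other settings, also set beforehand, were other pseudocounts, no filter or a filter at a mean of 100, scaling to 1 total, quantile normalisation, array weights, robust variance moderation, the replicate number as a block, fits on the compared groups alone, each library left out in turn, and edgeR 4.0.16 (quasi-likelihood, TMM) and DESeq2 1.42.0 on the recovered reads. Scaling to 1 total changes values little by construction, since the deposited columns, used in the main tests, already sum to nearly equal totals. Settings chosen after seeing the data were the displaced library realigned or as deposited, and leaving out pairs of libraries poor in cerebellar transcripts (young vehicle replicate 1 and old apigenin replicate 3) or rich in Malat1 (old vehicle replicate 4 and old apigenin replicate 5). Tables and figures were made with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.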

Results

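Polyadenylated RNA was sequenced from brains, whole per the labels, of male C57BL/6N mice aged 6 months (young) or 27 months (old). Mice drank either apigenin, a flavone found in plants, at 0.5 mg/mL in water thickened with 0.2% carboxymethylcellulose, or the thickened water alone (vehicle). The comparisons used 17 libraries: 4 from young vehicle mice, 3 from young apigenin mice, 5 from old vehicle mice and 5 from old apigenin mice. An additional young apigenin library, replicate 3, was left out because its values stood beside the wrong gene names in part of the table. Each library came from a separate mouse per the labels, so the p-values of single genes and of exact permutations rest on the spread between mice. Those of camera with the preset correlation assume how far the genes of a list vary together. They do not measure that shared variation between mice, and small values are to be read with this limit. Libraries held 28171596 to 41145635 reads assigned to genes, and 17978 to 19018 genes had a value above 0. Values are normalised read counts, and 15808 genes with a mean of at least 10 were tested. Differences are on the log2(value + 1) scale, which understates the change of low genes. Ddx3y, a gene of the Y chromosome, lay between 1392.6 and 2108.6 in the 17 libraries, and Xist, expressed from the inactive X chromosome of females, was at most 9.5. Adjusted p-values of genes are from limma with Benjamini-Hochberg adjustment, all two-sided, and coordinates are on mouse build GRCm38.

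How the brain transcriptome differed with age was read from old against young vehicle mice. Genes of activated microglia and the interferon response rose in the old brain, as did C4b of complement. C4b, which encodes complement component 4 (chromosome 17, 34728380 to 34743882), rose 4.31-fold, from a normalised read count of 1210 ± 145 (SD, n = 4) to 5300 ± 1270 (SD, n = 5), a log2 difference of 2.11 ± 0.13 (SE; adjusted p = 5.18e-08, limma). Clec7a, the receptor dectin-1 of activated microglia (chromosome 6, 129461591 to 129472779), rose 6.26-fold, from 16.8 ± 5.42 to 110 ± 29.2 (adjusted p = 5.82e-06). Gabra2, a subunit of the GABA-A receptor (chromosome 5, 70957597 to 71095849), fell 3.4-fold, from 2650 ± 201 to 796 ± 171 (adjusted p = 1.59e-06). Strain and age could not be told apart for Gabra2, nor for Wdfy1 and Nnt named below, as given under Other observations. In all, 622 of the 15808 genes passed an adjusted p of 0.05 in limma, 495 higher (79.6%) and 127 lower in old mice, and 3072 had an unadjusted p under 0.05. The median log2 difference over all tested genes was 0.0389. The share higher depended on the processing and was smaller with quantile normalisation, edgeR and DESeq2, as given below.

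Among the other genes with the smallest adjusted p, Mpeg1, a perforin-like protein of macrophages (chromosome 19, 12460779 to 12465283), rose 1.98-fold (log2 0.98 ± 0.08 SE, adjusted p = 2.27e-06). Lag3, an inhibitory immune receptor that binds MHC class II, rose 2.03-fold (adjusted p = 1.03e-05). Il33, an alarmin cytokine (chromosome 19, 29925114 to 29960718), rose 1.65-fold, from 1950 ± 175 to 3200 ± 162 (adjusted p = 2.92e-05). The integrin gene Itgax rose 9.44-fold and Cst7, which encodes the protease inhibitor cystatin F, rose 14.6-fold, from 3.76 ± 2.95 to 56.1 ± 20.8 (adjusted p = 6.29e-05 and 8.2e-05). AF251705 rose 2.13-fold, and Adss, an enzyme of purine synthesis, rose 1.37-fold. The protocadherin gene Pcdhb9 rose 1.81-fold (adjusted p = 5.82e-06), an uncertain value because reads may be shared with the other Pcdhb genes. Wdfy1, an endosomal adaptor of Toll-like receptors (chromosome 1, 79702262 to 79776143), fell 3.96-fold, from 2300 ± 170 to 591 ± 147 (adjusted p = 6.8e-07). Nnt, the mitochondrial nicotinamide nucleotide transhydrogenase (chromosome 13, 119335448 to 119408997), fell 2.3-fold, from 1320 ± 36.9 to 581 ± 109 (adjusted p = 1.82e-05), and Cd59a, an inhibitor of the complement attack complex, fell 2.33-fold (adjusted p = 0.00034). Sox11, a transcription factor of newborn neurons, fell 1.5-fold, from 940 to 628, and Gpr17, a receptor of maturing oligodendrocyte precursors, fell 1.86-fold, from 1810 to 985 (adjusted p = 0.000473 and 0.000671). Smaller falls were those of Dcakd (1.42-fold), the polyadenylation factor Fip1l1 (1.28-fold), the transcription factor Maz (1.21-fold) and the phosphatase Ppm1h (1.2-fold).

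**Figure D1:**
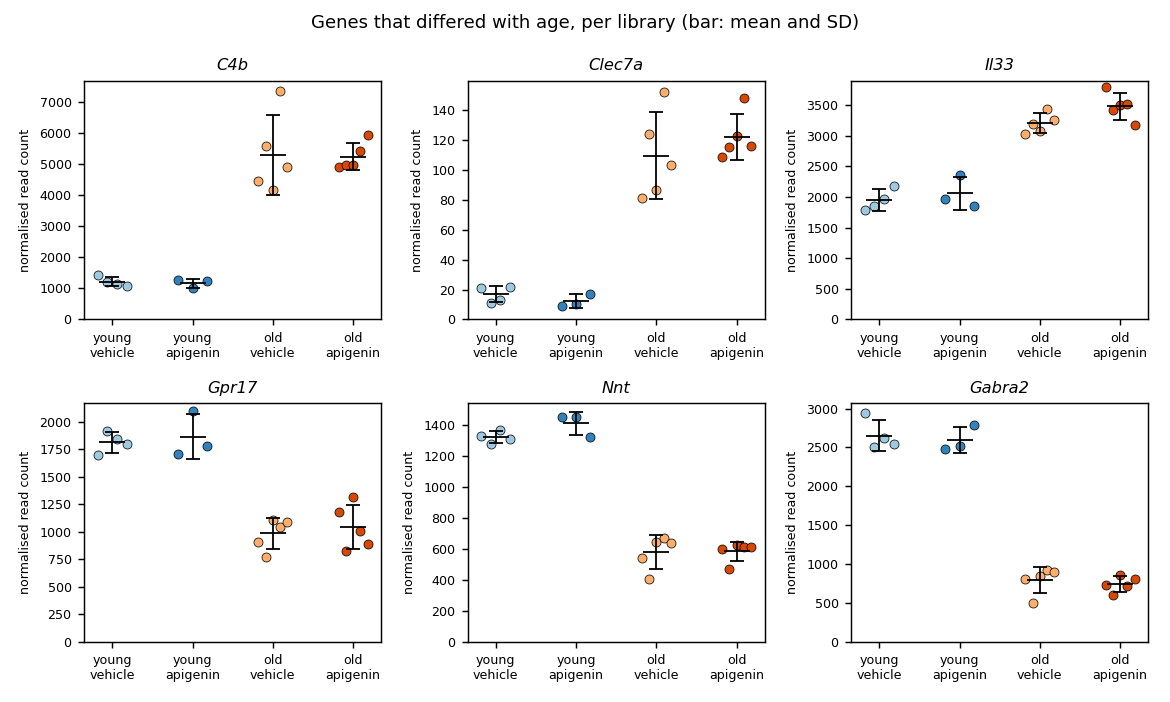
Normalised read counts of C4b, Clec7a, Il33, Gpr17, Nnt and Gabra2 in each of the 17 libraries, by age and treatment (points: libraries, bars: mean and SD). C4b averaged 1210 in young vehicle and 5300 in old vehicle mice, and the old libraries held 407 to 672.9 for Nnt against 1278.2 to 1453.3 in the young. For Nnt and Gabra2 strain and age could not be told apart.

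Immune lists moved with age as sets, and 3 of them kept their call with an estimated correlation between genes. Of 36 type I interferon genes, 25 rose and 0 fell (34 and 0 adjusted over the list alone), with a median log2 difference of 0.84 (camera adjusted p = 3.6e-28, adjusted p = 0.0213 with an estimated correlation). Among them Lgals3bp rose 2.18-fold, Ifit1 2.55-fold from 91.5 to 235, the interferon regulatory factor Irf7 2.36-fold, and Oas1a 3.32-fold, while Ifit1 and Oas1a have close paralogs that could share reads. Of 27 genes of activated or disease-associated microglia, 17 rose and 0 fell (21 and 0 adjusted over the list alone), with a median of 0.81 (camera adjusted p = 2.04e-22, adjusted p = 0.0213 with an estimated correlation). Lyz2, which encodes lysozyme, rose 2.54-fold. Of 14 genes of MHC class I antigen presentation, 10 rose and 0 fell (11 and 0 adjusted over the list alone), with a median of 0.58 (camera adjusted p = 5.51e-13, adjusted p = 0.0435 with an estimated correlation). H2-Q4 rose 2.44-fold, H2-K1 1.77-fold, the peptide transporter Tap1 2.16-fold and the immunoproteasome subunit Psmb8 1.99-fold, with H2 genes uncertain because their sequences are alike. Of 15 complement genes 5 rose and 1 fell (9 and 1 adjusted over the list alone), with a median of 0.50 (camera adjusted p = 9.43e-06, adjusted p = 0.176 with an estimated correlation). C3 rose 2.5-fold and its fragment's receptor C3ar1 2.26-fold, C1qa rose 1.42-fold, and C1qc, named after its values were seen, had a log2 difference of 0.50. Of 29 genes of NF-kB and innate sensing, 6 rose and 0 fell (9 and 0 adjusted over the list alone), with a median of 0.24 (camera adjusted p = 0.000161, adjusted p = 0.0666 with an estimated correlation). These included the adhesion molecule Icam1 at 2.17-fold, the endotoxin co-receptor Cd14 at 1.69-fold, Casp1 at 1.61-fold and the NF-kB subunit Rela at 1.21-fold. Of 17 cytokines and chemokines only Il33 passed over all genes (6 higher, and Cx3cl1 lower, adjusted over the list alone), and the list passed with a median of 0.27 (camera adjusted p = 0.0232, adjusted p = 0.176 with an estimated correlation), a call lost without old vehicle replicate 3 (0.0548).

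Glial and neuronal lists also moved with age under camera's preset correlation of 0.01, and none of those in these sentences kept its call with an estimated correlation. Of 23 genes of reactive astrocytes, 6 rose and 0 fell (11 higher, and Hspb1 lower, adjusted over the list alone), with a median of 0.41 (camera adjusted p = 9.16e-06, adjusted p = 0.206 with an estimated correlation). Gfap, the intermediate filament of astrocytes, rose 1.58-fold from 9890 to 15700, the protease inhibitor Serpina3n 1.73-fold, and the oncostatin M receptor Osmr 1.73-fold. Of 20 genes of myelinating oligodendrocytes, 10 rose and 0 fell (15 and 0 adjusted over the list alone), with a median of 0.32 (camera adjusted p = 5.75e-11, adjusted p = 0.169 with an estimated correlation). Opalin rose 1.55-fold, Aspa, which encodes aspartoacylase, 1.39-fold, and the myelin gene Mobp 1.35-fold. Of 13 genes of oligodendrocyte precursors Gpr17 and Neu4 fell and 0 rose, the same 2 adjusted over the list alone. That list's median was 0.01 although its mean of -0.16 and its test were downward (camera adjusted p = 0.013, adjusted p = 0.256 with an estimated correlation). Of 16 genes of newborn neurons and proliferation, Sox11, Sox4 (1.47-fold) and Top2a (1.88-fold) fell (6 adjusted over the list alone), with a median of -0.33 (camera adjusted p = 3.22e-08, adjusted p = 0.0762 with an estimated correlation). Of 15 general neuron genes Syn1, a synaptic vesicle protein, fell 1.21-fold (3 lower adjusted over the list alone, which adds Vamp2 and Tubb3), with a median of -0.14 (camera adjusted p = 7.9e-05, adjusted p = 0.152 with an estimated correlation). Nptx2, an activity-regulated pentraxin, fell 1.73-fold among 20 glutamatergic synapse genes (2 lower adjusted over the list alone, with Dlg4), whose median was -0.08 (camera adjusted p = 0.000173, adjusted p = 0.317 with an estimated correlation). None of the 20 activity-regulated immediate early genes passed over all genes (8 lower adjusted over the list alone), with a median of -0.33 (camera adjusted p = 4.28e-06, adjusted p = 0.295 with an estimated correlation), which was -0.18 without old vehicle replicate 3.

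Lists of protein folding, matrix and brain regions followed, again with no call kept under an estimated correlation. Of 17 heat shock genes Dnajb1 fell 1.37-fold and Hsph1 1.38-fold (7 lower adjusted over the list alone), with a median of -0.20 (camera adjusted p = 4.03e-09, adjusted p = 0.176 with an estimated correlation). Of 22 genes of the unfolded protein response 6 fell and 0 rose (10 lower adjusted over the list alone, with the stress-response genes Atf4, Trib3 and Asns higher), with a median of -0.21 (camera adjusted p = 9.16e-06, adjusted p = 0.315 with an estimated correlation). The chaperone genes Hspa5, Calr, Pdia4 and Hyou1 fell 1.45-, 1.38-, 1.35- and 1.18-fold. Of 21 genes of collagens and matrix assembly Serpinh1, a collagen chaperone, fell 1.56-fold and Col3a1 1.86-fold, the same 2 adjusted over the list alone, with a median of -0.17 (camera adjusted p = 0.0038, adjusted p = 0.519 with an estimated correlation). Of 23 genes of cholesterol synthesis 3 rose and 0 fell, the same 3 adjusted over the list alone, among them Insig1 at 1.31-fold and Lss at 1.39-fold, with a median of 0.07 (camera adjusted p = 0.0399, adjusted p = 0.658 with an estimated correlation). Of 77 cytosolic ribosomal protein genes Rps15a rose 1.16-fold (0 adjusted over the list alone), with a median of 0.15 (camera adjusted p = 3.9e-05, adjusted p = 0.692 with an estimated correlation). None of the 17 brainstem genes passed over all genes (9 lower adjusted over the list alone), and the median was -1.07 (camera adjusted p = 9.61e-08, adjusted p = 0.295 with an estimated correlation). The brainstem list averaged 6.25 to 7.235 in the young vehicle libraries. It averaged 7.21 in old vehicle replicate 2 and 3.81 to 5.26 in the other old vehicle libraries (exact permutation p = 0.0556, 0.102 adjusted over the lists). Hoxb5, a homeobox gene of hindbrain and spinal cord, held 0 to 293 across the 17 libraries. It held 137 to 293 in young vehicle mice and 277.9 in old vehicle replicate 2, against 0 to 4.9 in the other old vehicle libraries. Its values were 9.5 to 246.6 in young apigenin and 0 to 282.6 in old apigenin mice. Whether the libraries held unlike shares of hindbrain was not tested, and for this list such shares cannot be told apart from age. Lower medians without a called gene were those of choroid plexus (-0.41), ependymal cells (-0.23) and cortex and hippocampus (-0.08), with camera adjusted p = 4.12e-07, 0.00693 and 0.00733, and adjusted p = 0.352, 0.455 and 0.41 with an estimated correlation. Adjusted over the list alone, the choroid plexus genes Kcne2, Prlr, Cldn2 and Calml4 were lower and 0 genes of the other 2 lists passed. Calls were lost for ependymal cells and for cortex and hippocampus without young vehicle replicate 1 (camera adjusted p = 0.0531 and 0.111) and for cholesterol synthesis without old vehicle replicate 3 (0.176). The collagen median was -0.08 without old vehicle replicate 3 and the ribosomal median 0.09 without old vehicle replicate 2. Old vehicle replicate 4 pulled the collagen list the other way, at 9.329 against 8.464 to 8.846 in the other old vehicle libraries. In total 22 of 44 lists tested passed camera's preset correlation, 10 upward and 12 downward.

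Of 27 measured genes fixed for their roles in ageing or apigenin response, 15 rose and 0 fell with age in limma. Trem2, B2m, Cd68 and Lcn2 rose 1.67-, 1.47-, 1.75- and 6.11-fold, Lcn2 with a wide spread (109 ± 120 SD in old vehicle mice). The NADase gene Cd38 had a log2 difference of -0.01 (adjusted p = 0.989), the NAD salvage enzyme gene Nampt 0.15 (adjusted p = 0.179), and Cdkn1a, which encodes the cell cycle inhibitor p21, -0.38 (adjusted p = 0.276). Among 23 genes of NAD metabolism and sirtuins 0 passed, and the list did not pass camera (adjusted p = 0.678). Homeostatic microglia (camera adjusted p = 0.724), astrocytes (0.936), oxidative phosphorylation (0.752), NRF2 targets (0.961) and senescence (0.961) did not pass either. The mean of the senescence list was nevertheless higher in every old than in every young vehicle library, by 0.24 on average (exact permutation p = 0.0079, 0.0291 after adjustment over 44 lists), with a median of 0.06 over its 19 genes and 1 called. The list includes Mmp12, a macrophage elastase gene near the floor in young mice, whose rise with age is given under Other observations. That rise weighs on the mean more than on the median, and the list was not tested without Mmp12. The adjusted exact p of 0.0291 was also reached by interferon, activated microglia, MHC class I, complement, cytokine, NF-kB, myelin, newborn neuron, heat shock, cholesterol and lysosome lists. It was 0.0437 for reactive astrocytes, oligodendrocyte precursors, choroid plexus and the unfolded protein response. Other lists that passed camera had 0.0582 (general neurons) to 0.493 (collagens), with 0.102 for brainstem and 0.277 for immediate early genes. Quantile normalisation gave 282 higher and 157 lower genes (64.2% higher), edgeR with TMM scaling 328 and 178 (64.8%), DESeq2 582 and 446 (56.6%), and array weights 1325 and 676 (66.2%). The count of 622 was 246, 294 and 316 without young vehicle libraries 2, 3 and 4, and 375, 329, 401 and 407 without old vehicle libraries 1, 2, 4 and 5.

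**Figure D2:**
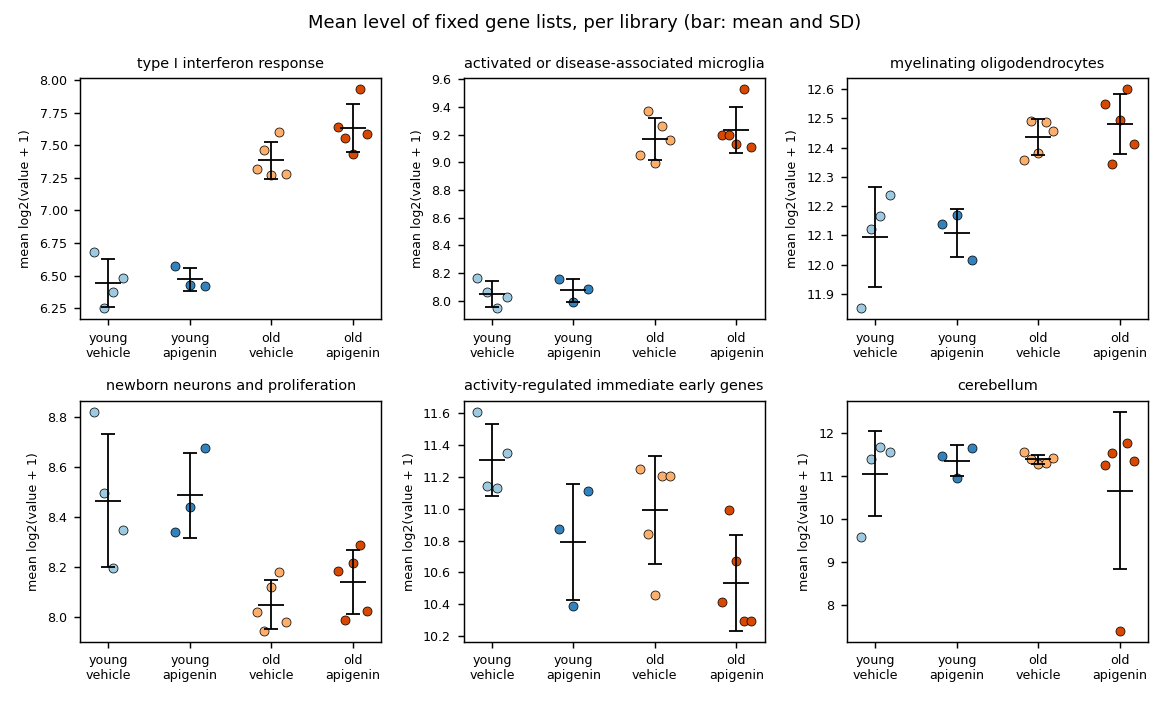
Mean log2(value + 1) of the genes of 6 fixed lists in each of the 17 libraries, by age and treatment (points: libraries, bars: mean and SD). Interferon and activated microglia lists were higher in every old than in every young library, and the cerebellum list was at 7.40 in old apigenin replicate 3 and 9.59 in young vehicle replicate 1.

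Whether apigenin altered the old brain was asked by comparing old apigenin with old vehicle mice, 5 against 5. No gene passed in limma (0 of 15808, smallest adjusted p = 0.986), 381 genes had an unadjusted p under 0.05, where 790 would be given by chance for independent genes, and edgeR and DESeq2 each called 0. Genes of microglia, complement and astrocytes that rose with age had no call for apigenin. C4b averaged 5300 ± 1270 (SD, n = 5) in vehicle and 5240 ± 442 (SD, n = 5) in apigenin mice, a log2 difference of 0.01 ± 0.12 (SE). Clec7a differed by 0.19, Cst7 by 0.20, Cd68 by -0.06 and Gfap by 0.22 ± 0.14 on the log2 scale. Without old apigenin replicate 4 the values were 0.12 for Clec7a, 0.05 for Cst7 and 0.12 for Gfap. Cd68 was at 0.02 without old vehicle replicate 4.

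The 5 genes with the smallest unadjusted p on each side are given as values, all with adjusted p = 0.986 in limma. Irf7, a master regulator of type I interferon genes (chromosome 7, 141262706 to 141266481), averaged 180 ± 29.5 in vehicle and 260 ± 38 in apigenin mice, a ratio of 1.44. Pgpep1l (chromosome 7, 68236610 to 68264233) averaged 17.7 ± 3.18 and 32.9 ± 4.05, Metrnl, a secreted cytokine-like protein, 192 and 250, the sphingosine phosphate receptor gene S1pr2 83.4 and 108, and Fam212a 50.1 and 74.1. Ppp1r10, a nuclear subunit of protein phosphatase 1 (chromosome 17, 35916434 to 35932283), averaged 1900 ± 89.7 in vehicle and 1550 ± 116 in apigenin mice, a log2 difference of -0.29 ± 0.06 (SE). Zfp341, Tbata, Nlrx1 and Pbld2 averaged 437, 187, 310 and 31.8 in vehicle and 372, 126, 248 and 20.9 in apigenin mice. Of the 27 genes fixed for ageing and apigenin roles 0 passed and 2 had an unadjusted p under 0.05, namely Irf7 and Isg15. Cd38, which apigenin is known to inhibit as an enzyme, differed by 0.07 ± 0.18 (SE), Nampt by 0.09, Nqo1 by -0.03, Hmox1 by 0.16, Cyp1b1 by 0.22 and Nfkb1 by 0.07, where Cd38 was at -0.06 and Cyp1b1 at 0.05 without old apigenin replicate 4. Nqo1 was at 0.11 without old vehicle replicate 2, and Nfkb1 at 0 without old apigenin replicate 5.

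As sets, 19 of 44 lists passed camera in old mice with the preset correlation, 15 upward and 4 downward, and 0 with an estimated one. Type I interferon genes leaned upward, 33 of 36 positive with a median of 0.26 (camera adjusted p = 2.95e-11, adjusted p = 0.475 with an estimated correlation). None passed over all genes, and 5 were higher adjusted over the list alone, which were Irf7, Ifit1 (235 to 339 on average), Isg15 (72.2 to 112), Ifi27 and Rtp4, the last named after its values were seen. The mean of the list differed by 0.24 between the arms (exact permutation p = 0.0556, 0.863 after adjustment over 44 lists). Activity-regulated immediate early genes leaned downward, 18 of 20 negative with a median of -0.39 (camera adjusted p = 4.51e-13, adjusted p = 0.475 with an estimated correlation), with 0 genes passing over all genes or adjusted over the list alone. Nr4a1, a nuclear receptor induced by neuronal activity, averaged 5380 in vehicle and 3090 in apigenin mice, and Arc, a synaptic protein of the same class (chromosome 15, 74669083 to 74672570), 9510 ± 3100 and 5860 ± 1730 (SD, n = 5 each). Cytosolic ribosomal protein genes were positive in 76 of 77 (median 0.13, camera adjusted p = 4.21e-16) and nuclear-encoded oxidative phosphorylation genes in 69 of 70 (median 0.10, camera adjusted p = 1.18e-11), both with adjusted p = 0.667 with an estimated correlation. Without old apigenin replicate 4 these medians were 0.07 and 0.04. Old apigenin replicate 5 pulled the other way, with list means of 12.05 and 11.664. The other old apigenin libraries had 12.314 to 12.613 and 11.809 to 12.113. Cox6c, a subunit of cytochrome oxidase, and Rps12, a protein of the small ribosomal subunit, differed by 0.20 and 0.19, with Rps12 at 0.12 without old apigenin replicate 4.

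The other 15 lists had adjusted p = 0.667 with an estimated correlation and 0 genes passing over all genes or adjusted over the list alone. Lists with upward camera calls were brainstem (median 0.81, camera adjusted p = 0.000183), cholesterol synthesis (0.08, 0.000239), NRF2 and antioxidant enzymes (0.08, 0.000345), hypothalamus (0.23, 0.000345), choroid plexus (0.21, 0.00123), fibroblasts of meninges and vessels (0.19, 0.00123), MHC class I (0.11, 0.00755), reactive astrocytes (0.10, 0.0113), lysosome and autophagy (0.07, 0.0125), cytokines and chemokines (0.10, 0.0426), activated microglia (0.06, 0.046) and the unfolded protein response (0.07, 0.046). Downward calls were those of cerebellum (median -0.50, camera adjusted p = 0.000732), glutamatergic synapse (-0.07, 0.00752) and pericytes and smooth muscle (-0.22, 0.0125). Without old apigenin replicate 4, 11 of these 15 lists lost their call (camera adjusted p = 0.0535 to 0.81), all but brainstem, cholesterol synthesis (median 0.04), hypothalamus (median 0.13) and cerebellum. The cerebellum call was lost without old apigenin replicate 3, with a median of 0.11 (camera adjusted p = 0.562). In the cerebellum list Gabra6, a GABA-A receptor subunit of cerebellar granule cells, stood at 1 in old apigenin replicate 3 and between 1781.5 and 2847.7 in the other 4 old apigenin libraries. Brainstem genes such as Slc6a4, the serotonin transporter, and Tph2, of serotonin synthesis, differed by 0.74 and 0.81, and by 0.29 and 0.35 without old vehicle replicate 5. The mean difference of the brainstem list lay between 0.44 (without old apigenin replicate 4) and 1.38 (without old vehicle replicate 2), and the list averaged 3.74 in old apigenin replicate 3. In old apigenin replicate 2, the ribosomal RNA gene Rn45s took 3.36% of the values, and Malat1, a nuclear long non-coding RNA, was at 31422.1 in old vehicle replicate 4 and 23604.5 in old apigenin replicate 5, against 4560.4 to 14949.4 elsewhere. Lists named for aryl hydrocarbon receptor targets (camera adjusted p = 0.381), NAD metabolism (0.808), NF-kB (0.601), senescence (0.418) and complement (0.191) did not pass. In simulated data of the same size, with genes drawn independently, 71.6% of genes changed 1.5-fold were called in this comparison. Variation shared by many genes of a library was not simulated, so the share for the real data is not known. With array weights, which down-weight noisy libraries, limma called 988 genes, 657 higher and 331 lower. The largest weights were 5.62 for old apigenin replicate 1 and 3.57 for old vehicle replicate 1. Of 100 splits of the old libraries, the real one included, 5 called as many, so chance cannot be excluded.

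**Figure D3:**
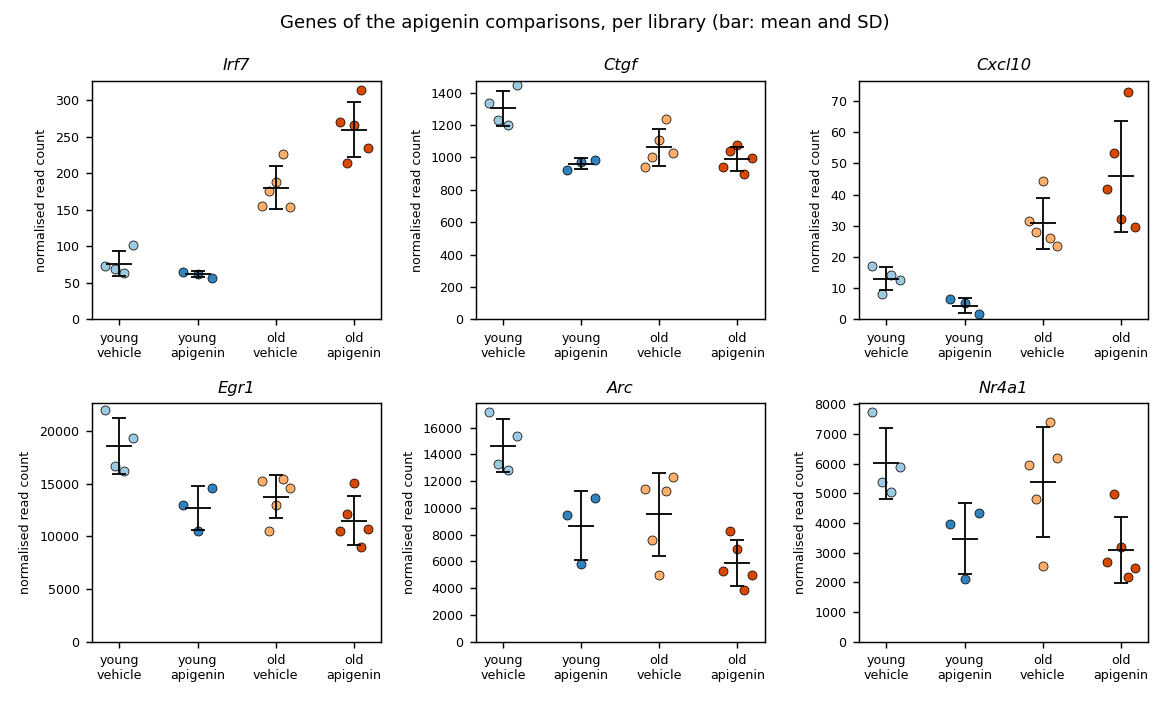
Normalised read counts of Irf7, Ctgf, Cxcl10, Egr1, Arc and Nr4a1 in each of the 17 libraries, by age and treatment (points: libraries, bars: mean and SD). Irf7 averaged 180 in old vehicle and 260 in old apigenin mice, and Arc 14700 in young vehicle and 8680 in young apigenin mice, with no adjusted p under 0.05 in limma for an apigenin comparison.

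In young mice apigenin was compared with vehicle in 3 against 4 libraries, which asks what the compound does without old age. No gene passed in limma (0 of 15808, smallest adjusted p = 0.999), 490 had an unadjusted p under 0.05, edgeR called 0 and DESeq2 called 1. The gene called by DESeq2 was Ctgf, a matricellular growth factor, with a log2 difference of -0.48 (adjusted p = 0.0187, DESeq2). Its values were 921.9 to 987.2 in young apigenin and 1203.5 to 1444.8 in young vehicle mice. Immediate early genes were the set with the smallest p, and all 20 had negative differences (adjusted p = 0.108 with an estimated correlation).

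Other genes with the smallest unadjusted p, all with adjusted p = 0.999 in limma, are given as values. Lhx9, a LIM homeobox transcription factor (chromosome 1, 138825186 to 138848577), averaged 274 ± 37.9 (SD, n = 4) in vehicle and 391 ± 57.4 (SD, n = 3) in apigenin mice. Ratios above 1 were those of Magohb, of the exon junction complex (1.43), the NF-kB modulator Nkiras2 (1.34), Txndc17 (1.32) and the proteasome subunit Psmc6 (1.17). Cxcl10, an interferon-induced chemokine (chromosome 5, 92346638 to 92348889), averaged 13 ± 3.74 in vehicle and 4.47 ± 2.48 in apigenin mice. Log2 differences were -0.75 for the immune GTPase gene Gimap6, -0.45 for Trib1 and -0.30 for Midn. C4b differed by -0.06 and Gfap by -0.13, or 0.05 and 0.03 without young apigenin replicate 2, and of the 27 fixed genes 0 passed and 0 had an unadjusted p under 0.05.

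With the preset correlation 11 of 44 lists passed camera in young mice, 3 upward and 8 downward, and 0 passed with an estimated one. The median of the immediate early genes was -0.50 (camera adjusted p = 1.15e-22, adjusted p = 0.108 with an estimated correlation), with 0 lower over all genes and 8 lower adjusted over the list alone. Egr1, a zinc finger transcription factor induced by activity (chromosome 18, 34859823 to 34864984), averaged 18600 ± 2670 in vehicle and 12700 ± 2100 in apigenin mice, a log2 difference of -0.55 ± 0.16 (SE). Egr4 differed by -0.63, Nr4a3 by -0.69 (-0.42 without young apigenin replicate 4) and Klf4 by -0.50. The mean of the list differed by -0.52 (exact permutation p = 0.0286, 0.629 after adjustment over 44 lists, where 0.029 is the smallest that 35 splits allow), and by -0.32 without young apigenin replicate 2. Striatum genes were negative in 12 of 13 (median -0.24, camera adjusted p = 3.42e-08, adjusted p = 0.815 with an estimated correlation), among them the dopamine receptor gene Drd1 at -0.33. Without young apigenin replicate 1 the striatum median was -0.03 and the call was lost (camera adjusted p = 0.567), with Drd1 at -0.09. Ribosomal protein genes were positive in 71 of 77 (median 0.11, camera adjusted p = 1.07e-05, adjusted p = 0.946 with an estimated correlation) and general neuron genes negative in 12 of 15 (-0.06, 0.00069, adjusted p = 0.586 with an estimated correlation). The neuron call was lost without young apigenin replicate 4 (median -0.02, camera adjusted p = 0.126). The hypothalamus list was positive in 11 of 14 (median 0.21, camera adjusted p = 0.0348), with Pmch, the precursor of melanin-concentrating hormone, higher adjusted over the list alone (74.4 to 125). The remaining passing lists were choroid plexus (median -0.16, camera adjusted p = 0.00381), oxidative phosphorylation (0.08, 0.0146), cortex and hippocampus (-0.05, 0.0159), glutamatergic synapse (-0.02, 0.0218), brainstem (-0.25, 0.0377) and cholesterol synthesis (-0.03, 0.0377). These 6 and the hypothalamus list had adjusted p = 0.946 with an estimated correlation, and of the passing lists only immediate early genes and hypothalamus had genes passing adjusted over the list alone. Without young apigenin replicate 2 the choroid plexus list passed upward (median 0.24, camera adjusted p = 0.00781). Calls of the other 6 were lost without young vehicle replicate 1 for cortex and hippocampus (camera adjusted p = 0.438) and glutamatergic synapse (0.325), without young apigenin replicate 4 for brainstem (0.556) and cholesterol synthesis (0.625), without young apigenin replicate 1 for oxidative phosphorylation (0.907) and without young vehicle replicate 4 for hypothalamus (0.127). Young vehicle replicate 1 held 166.3 for Gabra6, against 1607.4 to 3131 in the other 6 young libraries. NAD metabolism (camera adjusted p = 0.376), NRF2 targets (0.434) and interferon genes (0.376) did not pass, and for interferon genes the median of 0.03 and mean were positive while the test pointed downward. In simulated data of the same size, with genes drawn independently, 56.7% of genes changed 1.5-fold were called in this comparison.

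Old and young mice that both drank apigenin, 5 against 3 libraries, gave the age difference under treatment. C4b rose 4.51-fold, from 1160 ± 143 (SD, n = 3) to 5240 ± 442 (SD, n = 5), a log2 difference of 2.17 ± 0.14 (SE; adjusted p = 1.26e-07, limma). Clec7a rose 9.73-fold (adjusted p = 1.4e-06), Irf7 4.14-fold, from 61.7 to 260 (adjusted p = 1.6e-06), and Ifit1, an RNA-binding interferon effector (chromosome 19, 34640871 to 34650009), 4.3-fold (adjusted p = 2.23e-06). Wdfy1 fell 4.16-fold from 2320 to 566, Gabra2 3.51-fold from 2600 to 743, and Nnt 2.43-fold from 1410 to 583 (adjusted p = 1.4e-06, 2.3e-06 and 2.39e-05). For these falls strain and age could not be told apart here either. In limma 278 genes passed, 224 higher and 54 lower, and 2205 had an unadjusted p under 0.05.

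Further rises were those of Lag3 (2.3-fold), Mpeg1 (1.9-fold), Lgals3bp (2.64-fold), the lymphocyte receptor gene Ly9 (4.93-fold), Pcdhb9 (1.73-fold) and Il33 (1.7-fold). Further falls were those of Fip1l1 (1.27-fold), Gpr17 (1.81-fold), Ppp1r10 (1.33-fold, adjusted p = 0.00336), the dynein light chain gene Dynlt1b (2.9-fold), Cd59a (2-fold), the matrix gene Tnc (2.49-fold) and Hrk, a pro-apoptotic BH3 protein (1.43-fold). Cxcl10 rose 8.85-fold, from 4.47 to 45.8 (adjusted p = 8e-05). Of 36 interferon genes 26 rose and 0 fell (31 and 0 adjusted over the list alone), with a median of 1.21 (camera adjusted p = 1.85e-46, adjusted p = 0.00375 with an estimated correlation). Activated microglia had 17 of 27 genes higher (21 adjusted over the list alone, median 0.76, camera adjusted p = 4.98e-32, adjusted p = 0.00375 with an estimated correlation), MHC class I 8 of 14 (12 adjusted over the list alone, 0.73, 2.35e-16, adjusted p = 0.0182 with an estimated correlation), and cytokines and chemokines 4 of 17, which were Il33, Cxcl10, Ccl12 and Tgfb1 (6 adjusted over the list alone, 0.40, 7.29e-05, adjusted p = 0.0229 with an estimated correlation). Itgax rose 7.21-fold, Lyz2 2.88-fold, H2-K1 2.07-fold and B2m, the MHC class I light chain, 1.65-fold.

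Calls that did not hold with an estimated correlation included myelinating oligodendrocytes (7 of 20 higher, 15 adjusted over the list alone, median 0.36, camera adjusted p = 4.45e-16, adjusted p = 0.0691 with an estimated correlation), with Opalin at 1.56-fold and the tight junction gene Cldn11 at 1.31-fold. Reactive astrocytes had 5 of 23 higher (11 adjusted over the list alone, camera adjusted p = 1.57e-09, adjusted p = 0.0791 with an estimated correlation), namely Gfap (2-fold, from 9250 to 18300), Serpina3n (1.88-fold), Osmr, Ggta1 and, named after its values were seen, Iigp1. For complement 6 rose and 1 fell (7 and 1 adjusted over the list alone, camera adjusted p = 8.05e-08, adjusted p = 0.0815 with an estimated correlation). For NF-kB genes 3 rose, which were Icam1, Cd14 and Tlr2 (6 adjusted over the list alone, camera adjusted p = 0.000183, adjusted p = 0.0529 with an estimated correlation). Cholesterol synthesis had 4 of 23 higher, among them Insig1, Mvd and Hsd17b7 (9 adjusted over the list alone, median 0.20, camera adjusted p = 7.22e-09, adjusted p = 0.128 with an estimated correlation). Of lysosome and autophagy genes the protease gene Ctss rose 1.78-fold, Laptm5 1.29-fold and Grn, which encodes progranulin, 1.23-fold (8 higher, and Ulk1 lower, adjusted over the list alone, camera adjusted p = 1.05e-05, adjusted p = 0.249 with an estimated correlation). Circadian clock genes Bhlhe41, Nr1d1 and Bhlhe40 rose 1.48-, 1.26- and 1.4-fold (8 higher, and Arntl and Npas2 lower, adjusted over the list alone, camera adjusted p = 0.0101, adjusted p = 0.249 with an estimated correlation). Sox4 and Sox11 fell 1.62- and 1.34-fold among newborn neuron genes, the same 2 adjusted over the list alone (median -0.32, camera adjusted p = 4.92e-05, adjusted p = 0.17 with an estimated correlation). Hspa5 and Hyou1 fell in the unfolded protein response (12 lower adjusted over the list alone, with Atf4, Atf3, Trib3, Chac1 and Asns higher, median -0.26, camera adjusted p = 0.000871, adjusted p = 0.509 with an estimated correlation). Altogether 25 of 44 lists passed the preset correlation, 16 upward and 9 downward, and 4 with an estimated one. Counts were 149, 166 and 171 without young apigenin libraries 2, 4 and 1. DESeq2 called 485 genes, 340 higher (70.1%), against 80.6% higher in limma, and leaving out both Malat1-rich libraries gave 856, 444 higher and 412 lower (51.9% higher).

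Age differences in the vehicle and apigenin arms share no library and were compared gene by gene. They correlated across the 15808 genes with r = 0.588, where genes are not independent replicates. Passing genes numbered 216 in both arms, 179 higher where 7 would be shared by independent lists and 37 lower where 0.4 would be, and 0 had opposite signs. Of the 622 genes called in vehicle mice 610 (98.1%) had the same sign in apigenin mice, and 406 passed in the vehicle arm alone. Of the 278 called in apigenin mice 277 had the same sign in vehicle mice, and 62 passed in that arm alone. Passing in 1 arm alone does not show that the arms differ, which the interaction tested.

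**Figure D4:**
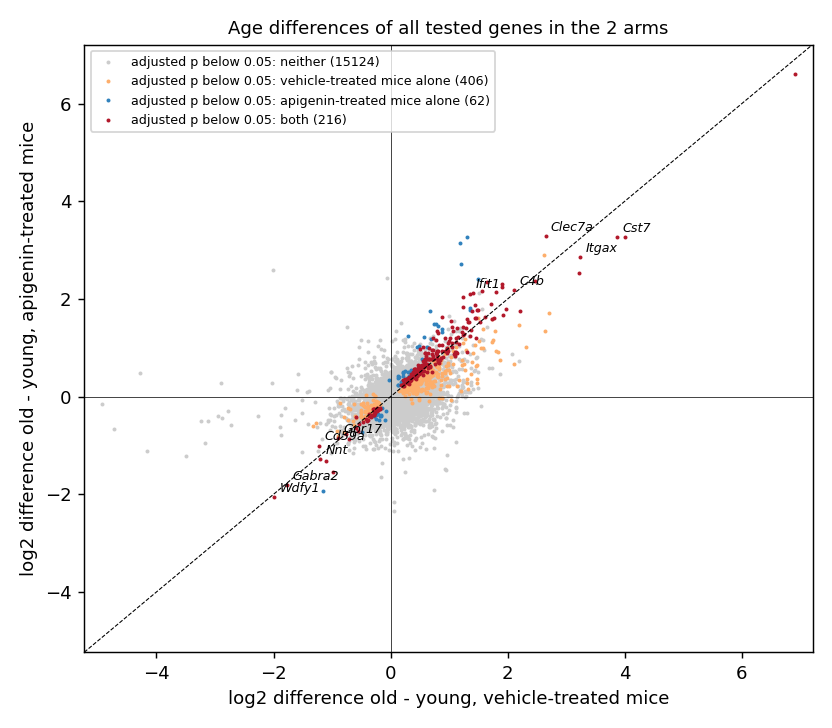
Log2 difference between old and young mice for each of 15808 genes in vehicle-treated (horizontal axis) and apigenin-treated mice (vertical axis), with colours for genes passing an adjusted p of 0.05 in both, either or neither arm and a dashed line of equal values. The 216 genes passing in both arms lie in the quadrants of equal sign, and r across genes is 0.588.

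The interaction asked whether apigenin acted differently at the 2 ages, and no gene passed. In limma 0 of 15808 passed (smallest adjusted p = 1), 196 had an unadjusted p under 0.05, and edgeR and DESeq2 called 0. Smallest p-values were those of Cxcl10, with a difference of log2 effects of 1.96 ± 0.49 (SE), and Irf7 with 0.81 ± 0.23, followed by Gimap6 (0.83), Tgfb1, which encodes transforming growth factor beta (0.36), and the mitochondrial assembly gene Coa7 (0.34). On the negative side stood Pbld2 (-1.07 ± 0.29), the non-coding Gt(ROSA)26Sor (-0.86), Nkiras2 (-0.49) and Sepsecs (-0.47), of selenocysteine tRNA synthesis. Interferon genes had a median difference of 0.16 (camera adjusted p = 7.43e-09, adjusted p = 0.674 with an estimated correlation, 0 adjusted over the list alone), and of 0.08 without old apigenin replicate 4. Of 17 cytokines and chemokines Cxcl10 and Tgfb1 were higher adjusted over the list alone and 0 over all genes (camera adjusted p = 0.0239, adjusted p = 0.674 with an estimated correlation), a call lost without old vehicle replicate 2 (0.111). In all 18 of 44 lists passed with the preset correlation, 17 upward and 1 downward, and 0 with an estimated one. In simulated data of the same size, with genes drawn independently, 25.4% of genes with a 1.5-fold difference of effects were called in this test.

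Whether apigenin moved the brain against the direction of age was tested over the genes of pooled aging, the mean of both old groups against the mean of both young groups. Pooled aging called 1913 genes in limma, 1259 higher (65.8%) and 654 lower, edgeR with TMM scaling 1036 and 842 (55.2% higher), and DESeq2 1293 and 1096 (54.1% higher). In old mice 836 of these (43.7%) had an apigenin difference opposed to age and 1077 the same sign (exact permutation p = 0.738). Across 15808 genes the apigenin difference in old mice correlated with pooled aging at r = -0.032 (exact permutation p = 0.635 over 252 assignments, where the smallest possible is 0.0079). In young mice 801 (41.9%) were opposed (exact permutation p = 0.171), and r was 0.194 (exact permutation p = 0.0286, with 0.029 the smallest that 35 assignments allow). Adjusted over these 2 correlations the exact p-values were 0.635 and 0.0571. Age differences from vehicle mice alone share those mice with the apigenin comparison. They gave r = -0.318 in old mice, where unchanged groups simulated against the same controls gave -0.474, with a covariance of -0.0179 against -0.0171. In young mice r was 0.456 against a simulated 0.489, with a covariance of 0.0301 against 0.0213. The simulated groups held no age difference, so simulated and real r are not on a par, and only the covariances can be compared. With the vehicle mice divided between the comparisons, median r was -0.003 in old and 0.112 in young mice. With a filter at a mean of 100, r in old mice was 0.068, and without old apigenin replicate 5 it was 0.033. Counts of pooled aging were 1271 without young apigenin replicate 2 and 1241 without young apigenin replicate 1.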

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

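The rule for libraries standing apart from their group and the interaction test were fixed beforehand, while leaving out the 2 libraries poor in cerebellar transcripts was chosen after the data were seen. A library was picked out where its gap to the nearest other library of its group was large against the range of the group. Of 288 group tests 19 picked out a library, and 14.4 would by chance, which picks out about 1 in 20 groups. The young apigenin group, with 3 libraries, was too small for the rule and was not tested. No explanation was tested for these values.

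Young vehicle replicate 1 stood apart in 5 measures. Its cerebellum list averaged 9.59 on the log2 scale against 11.40 to 11.68 in the other 3 libraries of its group. Its homeostatic microglia list averaged 9.71 against 9.49 to 9.52, and its ependymal list 6.93 against 6.60 to 6.62. Its normalised count was 6459.1 for Maz against 7046.8 to 7109.9, and 98.7 for Tbata against 167.3 to 173.6. Old vehicle replicate 2 also stood apart in 5 measures. Its homeostatic microglia list averaged 9.40 against 9.62 to 9.69, its glucocorticoid-responsive list 10.40 against 9.21 to 9.45, and its lysosome and autophagy list 11.57 against 11.46 to 11.49. It held 499.6 for Gabra2 against 813.7 to 920.6, and 118.8 for Tnc against 188.3 to 208.4.

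Old apigenin replicate 4 stood apart in 3 measures, with activated microglia at 9.53 against 9.11 to 9.20, Cst7 at 93.6 against 47.5 to 59.3 and Cd59a at 512.3 against 294.4 to 352.2. Old vehicle replicate 4 had GABAergic neuron genes at 11.61 against 11.81 to 11.87 and Cst7 at 92.9 against 43.1 to 51.5. The cerebellum list of old apigenin replicate 3 averaged 7.40 against 11.27 to 11.77. Blood cell genes in old vehicle replicate 5 averaged 3.96 against 6.20 to 7.03. Nnt was at 470.2 in old apigenin replicate 2 against 595.8 to 624.4 in the other 4, and Zfp341 at 405.4 in old apigenin replicate 5 against 360.8 to 365.9.

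The apigenin difference was set apart between the ages for 18 lists by camera's preset correlation, and for 0 with an estimated correlation (adjusted p = 0.674 to 0.881). Median log2 differences of the apigenin effect, old minus young, were 0.162 for interferon genes, 0.324 for choroid plexus, 0.552 for brainstem, 0.11 for cholesterol synthesis, 0.193 for fibroblasts of meninges and vessels, 0.078 for lysosome and autophagy and 0.189 for striatum. They were 0.077 for immediate early genes, 0.043 for cytokines and chemokines, 0.022 for oxidative phosphorylation, 0.47 for olfactory bulb, 0.222 for MHC class II and 0.049 for activated microglia. They were 0.034 for the circadian clock, 0.058 for reactive astrocytes, 0.079 for newborn neurons and 0.06 for heat shock proteins. With each library left out in turn only interferon genes, brainstem, cholesterol synthesis and lysosome and autophagy kept their camera call, and without old apigenin replicate 4 the medians of the last 2 were 0.06 and 0.01 (camera adjusted p = 0.000187 and 0.0498) and that of interferon genes 0.08. Without young apigenin replicate 1 the medians were -0.03 for striatum, 0.09 for olfactory bulb and 0.02 for newborn neurons (camera adjusted p = 0.45, 0.57 and 0.352). Without young apigenin replicate 2 they were -0.04 for choroid plexus, 0.04 for fibroblasts and -0.13 for immediate early genes (0.691, 0.39 and 0.578). Without old apigenin replicate 4 they were 0.09 for MHC class II, -0.04 for reactive astrocytes and -0.02 for oxidative phosphorylation (0.327, 0.548 and 0.935), and activated microglia lost their call (0.463). Heat shock proteins and the circadian clock lost theirs without young apigenin replicate 4 (0.557 and 0.225), and cytokines and chemokines without old vehicle replicate 2 (0.111). The cerebellum list had a median of -0.713, or -0.17 without old apigenin replicate 3 (0.525), and without the 2 libraries poor in cerebellar transcripts its call turned upward (camera adjusted p = 1.13e-06).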

How the results depend on the processing

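Alternatives with the displaced library, and those leaving out libraries poor in cerebellar transcripts or rich in Malat1, were chosen after the data were seen, and the others were planned. Genes with the smallest p and those of immune, glial, newborn neuron, stress and activity lists kept direction and side of the threshold in 1429 of 1565 alternative values for age in vehicle mice, with 108 weaker, 28 stronger and 0 reversed. The figures were 1273 of 1335 for age in apigenin mice (4 reversed), 830 of 853 for apigenin in old mice (0 reversed), 317 of 321 in young mice (3 reversed), 1010 of 1014 for the interaction (4 reversed) and 1295 of 1731 for the lists (2 passing in the other direction, 434 weaker). Over all genes picked by the naming rule, 42 of 495 differences turned sign without at least 1 library (3 of 118, 3 of 111, 11 of 107, 22 of 81 and 3 of 78 in that order), and 21 of 95 lists had a mean or median that did. For apigenin in old and in young mice and for the interaction no gene passed in the main tests. Staying on that side of the threshold was thus nearly given in advance. Part of the genes named there were also picked by p from the same data, which favours a stable sign.

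The 622 genes of age in vehicle mice were 402 with the compared groups alone, 2001 with array weights, 1028 with DESeq2, 156 with the displaced library as deposited, and 246 (without young vehicle replicate 2) to 646 (without old vehicle replicate 3) with 1 library left out. The 278 of age in apigenin mice were 130 with the compared groups alone, 2537 with array weights, 485 with DESeq2, 558 with the displaced library realigned, 856 without the Malat1-rich libraries, and 149 (without young apigenin replicate 2) to 389 (without old apigenin replicate 5) with 1 library left out. The 1913 of pooled aging were 4323 with array weights, 993 with the displaced library as deposited, 2919 without the Malat1-rich libraries, and 1241 (without young apigenin replicate 1) to 2215 (without old apigenin replicate 5). Apigenin in old mice called 988 genes with array weights, which gave old apigenin replicate 1 a weight of 5.62 and old apigenin replicate 5 one of 0.29, and 0 with each library left out. Apigenin in young mice called 1 with DESeq2 and 0 with each library left out, as did the interaction (0). Settings with fewer libraries or groups have less to estimate the spread from by construction, and for the rest the cause was not tested.

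Replicate numbers did not pair the libraries: over 22 same-numbered pairs r was -0.254 to 0.307, with 4 above 0.1, and 5 of 17 libraries correlated best with their own number. With the replicate number as a block, 388 genes were called for age in vehicle mice, 281 for age in apigenin mice, 1776 for pooled aging and 0 for each apigenin comparison and the interaction.

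Lists passing with an estimated correlation were 3 for age in vehicle mice, 4 for age in apigenin mice and 0 for apigenin in old mice, apigenin in young mice and the interaction. With fry these were 11, 12, 0, 0 and 0. The interaction gave 10 with quantile normalisation and 11 with the displaced library as deposited, which gave 4 for apigenin in young mice, and the cause was not tested. With 1 library left out the ranges were 21 to 27 (age, vehicle), 9 to 22 (apigenin, old; 9 without old apigenin replicate 4), 7 to 14 (apigenin, young; 7 without young apigenin replicate 4 or young vehicle replicate 2), 21 to 28 (age, apigenin) and 10 to 24 (interaction; 10 without young vehicle replicate 2, 11 without young vehicle replicate 1).

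Opposition to aging in old mice (r = -0.032) was 0.001 with a pseudocount of 8, 0.068 with a filter at 100, 0.063 without the Malat1-rich libraries, -0.318 with the age difference of vehicle mice and -0.065 to 0.033 with 1 library left out. In young mice (0.194) it was 0.456 with the age difference of vehicle mice, 0.118 realigned, -0.779 as deposited, 0.213 without the cerebellum-poor libraries and 0.149 to 0.217 with 1 library left out. Fewer assignments limit the exact p of those last settings, and for the others the cause was not tested.

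Single results past the threshold in the other direction were the choroid plexus list in young mice without young apigenin replicate 2 (camera adjusted p = 0.00781, with 3.3e-09 to 0.0225 over the libraries left out in turn), the cerebellum list of the interaction without the cerebellum-poor libraries (1.13e-06). Among the first genes above, Hspb1 turned in the interaction without young apigenin replicate 4 (-0.04, with up to 0.45 over the libraries left out). With the displaced library as deposited, log2 values were -0.16 for Nkiras2, -1.97 for Txndc17 and 0.06 for Trib1 (apigenin, young), -0.32 for Opalin, 1.51 for Olig2, 0.44 for Ptprz1 and 0.32 for Pdia6 (age, apigenin), and 0.09 for Nkiras2, -0.45 for Rsad2 and -0.54 for Srgn (interaction). Those genes lie past the break and so took other genes' values. Depth of 28171596 to 41145635 reads limits genes near the filter, such as Cxcl10 at 4.47 in young apigenin mice.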

Other observations

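Tests of neuron share, of strain, of chance assignment of mice to arms and of other splits of the libraries were chosen after the results were seen, while those of regional share, transcript length and the splits with array weights were set down before their values were seen. In both arms vascular and other genes outside the lists described so far passed with age. Vwf, the von Willebrand factor of endothelium, and Ly6a, also of endothelium, rose in vehicle mice by 0.93 and 0.66 and in apigenin mice by 0.93 and 0.78 on the log2 scale. They were the called genes among 16 endothelial genes in each arm (4 in vehicle and 2 in apigenin mice adjusted over the list alone). The list had camera adjusted p = 0.0526 in vehicle mice and 0.0286 in apigenin mice (adjusted p = 0.616 with an estimated correlation), the latter call lost without young apigenin replicate 4 (camera adjusted p = 0.228). Named after their values were seen, the neuropeptide gene Cort rose by 1.31 in vehicle and 0.92 in apigenin mice, and the macrophage elastase gene Mmp12 rose from 0.459 to 23.8 on average in vehicle and from 1.21 to 19.2 in apigenin mice. Ahrr, the repressor of the aryl hydrocarbon receptor, rose by 1.80 in vehicle mice, also named after its values were seen.

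In apigenin mice further lists passed camera with age but not with an estimated correlation. MHC class II genes had 0 called over all genes, with Cd74, H2-Ob, H2-DMb1 and H2-Aa higher adjusted over the list alone (median 0.63, camera adjusted p = 0.00269, adjusted p = 0.292 with an estimated correlation). Among precursors of oligodendrocytes Gpr17 fell, joined by Olig2 adjusted over the list alone (median -0.15, camera adjusted p = 0.0286, adjusted p = 0.293 with an estimated correlation), a call lost without young apigenin replicate 2 (0.1). Lists with 0 called genes were heat shock proteins (median -0.19, camera adjusted p = 1.11e-05), general neurons (-0.08, 0.0126), glutamatergic synapse (-0.13, 0.000237), immediate early genes (-0.22, 0.0119), collagens (-0.27, 0.0175) and cerebellum (-0.43, 0.0339). Ribosomal proteins (median 0.15, camera adjusted p = 4.78e-09), striatum (0.18, 0.0312) and glucocorticoid-responsive genes (0.22, 0.0339) were upward, the last with Lcn2 adjusted over the list alone. For these 9 lists adjusted p = 0.293 to 0.682 with an estimated correlation. Striatum turned to a median of -0.09 without young apigenin replicate 1 (camera adjusted p = 0.397) and cerebellum to 0.11 without old apigenin replicate 3 (0.747). Calls were also lost for general neurons without young apigenin replicate 2 (0.135), for immediate early genes (median -0.05, 0.0947) and glucocorticoid-responsive genes (0.08, 0.998) without young apigenin replicate 4 and for collagens without young apigenin replicate 1 (0.105). Medians were -0.05 for glutamatergic synapse and 0.10 for ribosomal proteins without old apigenin replicate 4, and -0.10 for heat shock proteins without young apigenin replicate 1. Other libraries pulled the other way. Ribosomal proteins averaged 12.05 in old apigenin replicate 5, against 12.314 to 12.613 in the rest of its group. Immediate early genes averaged 10.392 in young apigenin replicate 2, against 10.87 and 11.111.

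Gene counts were set against other splits of the same libraries into groups of the same sizes. For age in vehicle mice 1 of 100 splits, the real one, called as many as 622 genes, and the highest other called 236. Nor did another split reach the real count for age in apigenin mice (278, 1 of 56 splits, highest other 33) or pooled aging (1913, 1 of 100, highest other 0). Chance is thus unlikely for these counts but not excluded. The other splits mix old and young mice, so an age difference widens the spread within their groups and lowers their counts. For apigenin in old mice (0 genes, 100 of 100 splits), apigenin in young mice (0, 35 of 35, highest other 0) and the interaction (0, 100 of 100, highest other 0) every split calls as many as 0, so these counts say nothing on chance. In old mice 1 split called 1885. That split set old apigenin replicates 1, 3 and 4 with old vehicle replicates 2 and 3 against the other 5 old libraries. It mixes the arms. In the first set Malat1 was at 4560.4 to 8397.6, against 8852 to 31422.1 in the other. The oxidative phosphorylation list averaged 11.825 to 12.113 in the first set, against 11.625 to 11.809. The split was singled out because it called the most genes, and why it did so was not tested. With array weights 5 of 100 splits called as many as the 988 genes, the highest other 2039, and chance cannot be excluded. Counts of passing lists did not exclude chance either: 22 in 11 of 100 splits for age in vehicle mice (highest other 25), 25 in 10 of 56 for age in apigenin mice (29), 19 in 21 of 100 for apigenin in old mice (24), 11 in 32 of 35 in young mice (21) and 18 in 30 of 100 for the interaction (26). The median of the other splits was 16, 19, 15, 14 and 15 lists in that order.

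Nnt, Gabra2 and Wdfy1 were lower in every old than in every young library, at 407 to 672.9 against 1278.2 to 1453.3, 499.6 to 920.6 against 2485.4 to 2943.7 and 464.2 to 839.6 against 2090.9 to 2484.1. Fewer neurons in the old brains would lower neuronal genes alike, but the general neuron list had a median of -0.14 with an interquartile range of 0.1, far from the falls of these 3 genes. A difference of substrain between young and old mice may account for them, since Nnt and Gabra2 transcripts are known to be lower in C57BL/6J than in C57BL/6N mice, the strain the labels give for all. In a search for genes at 1 read or fewer in all libraries of 1 age and at 10 or more in all of the other, 1 gene was found, Gm15446 (chromosome 5, 109923400 to 109943936), at 0 in all young and 67.5 to 221.5 in all old libraries, and 0 genes were found between the arms. Strain and age cannot be told apart here, because every old mouse would differ from every young mouse in both, and an age difference stays open. A strain difference would also enter the counts of genes called with age in both arms, and their agreement.

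Immediate early genes had lower means in apigenin than in vehicle mice at both ages, with a log2 difference of -0.49 averaged over the ages. Different shares of cortex and striatum in the tissue would shrink this difference once accounted for, but with both list means as covariates it was -0.53 ± 0.16 (SE), against -0.49 ± 0.15 without. Chance assignment of mice to arms could account for it: exact permutation within age gave p = 0.00465 over 8820 reassignments, and 0.205 after adjustment over 44 lists. An effect of apigenin stays open as untested.

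Ribosomal protein and oxidative phosphorylation genes were slightly higher in apigenin mice of both ages, with medians of 0.125 and 0.10 in old mice. The oxidative phosphorylation list also separated, without overlap, the 2 sets of old libraries in the split with 1885 called genes, which mixes the arms. Short transcripts may gain when RNA integrity differs, and genes outside the lists matched for length and level had a median of 39.3% of the ribosomal and 52.4% of the oxidative phosphorylation median in old mice, and 9.4% and 25.5% in young mice. Median exon lengths were 977 and 983 for the 2 lists and 1534 and 1596 for the matched genes, so the match fell short and length remains undecided for the ribosomal and oxidative phosphorylation genes. Chance assignment could also account for them, with an exact permutation p of 0.0791 for the ribosomal list and 0.614 after adjustment over 44 lists. An effect of apigenin stays open as untested.

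Some values stood out in 1 or a few libraries. Alb, which encodes serum albumin made in liver, was at 913.8 in old vehicle replicate 5 and 776.4 in old apigenin replicate 5, against a median of 33.3. Gh and Prl, hormones of the pituitary, were at 344.9 and 54.6 in young vehicle replicate 1 and at 151.2 and 18 in old apigenin replicate 4, and Gh was at 50.5 or less elsewhere. Col1a1 was at 1068.3 in old vehicle replicate 4, against a median of 356.2. Rn45s and Lars2 were at 1128461.5 and 21709.3 in old apigenin replicate 2. Lcn2 was at 364.8 in old apigenin replicate 4 and 321.9 in old vehicle replicate 2. Hbb-bs and Hba-a1, which encode haemoglobin, were listed at 0 in all 17 libraries.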
